A study of Homo sapiens with 6 samples.

How the data were processed

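The 6 libraries, 3 of PANC-1 cells kept for 48 h with 8 µM CMR and 3 control, were made from poly(A)-selected RNA and sequenced as paired-end reads, per the labels' protocols. The same protocol text names an adipose source and both poly(A)- and poly(A)+ fractions, which do not match the other labels; the cell line given in the labels was used here. What the control cells received, the strandedness of the libraries and the full name of CMR were not given in the sources used here.

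The table as deposited holds, per the file headers, a count and an FPKM value for each of 58825 genes and 6 libraries. The deposited count values are whole numbers without normalization, and whether the authors tallied reads or rounded an assembler's estimate was not given in the sources used here. The deposited FPKM values were scaled by the authors to gene length and library size, with genes of no count listed at 0.0001, and their sums ran from 228402 to 249649 per library. The submitters' processing notes list Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0, with the mouse build mm8. The gene identifiers are human, and of 58552 genes whose identifier is in GENCODE release 29, 47593 (81.3%) have the same chromosome, start and end as in that annotation of human build GRCh38, so coordinates were read as GRCh38. The table had 0 columns of no sample.

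The design, fixed before the data were examined, assumed FPKM alone, with a switch to counts if the table held them. Counts were therefore tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr (minimum count 10, minimum total 15), a quasi-likelihood test and Benjamini-Hochberg adjustment over the 19200 genes kept of 31368 with any count. A gene was called at an adjusted p under 0.05, and changed at least 2-fold if also past a log2 fold change of 1. Normalised expression (CPM, counts scaled to library size) used the same factors. Library totals, from 51147268 to 70129221 counts, and 3 libraries per group set the precision. In simulated counts for the same 19200 genes and libraries, with 50 genes changed at each size, 0% were recovered at 1.5-fold, 26% at 2-fold, 76% at 4-fold and 84% at 8-fold, with 4 false calls among 97. With no gene changed, 1 gene was called and 4.65% of genes had an unadjusted p under 0.05. The recovery simulation changed far fewer genes than the 7404 called in the data. The adjusted threshold is stricter when fewer genes change, so recovery in the data can be higher than the simulated shares. Protein-coding genes held 96.5 to 97.1% of counts. No 2 libraries were copies of each other.

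Gene lists were written before the data were examined. Of 892 members, 796 were matched by symbol. The 43 lists with at least 5 tested members were tested with limma 3.58.1's camera with a preset correlation of 0.01, adjusted over the lists. It was run on edgeR's conversion of the counts to normal scores under a negative binomial model. The test was repeated with the correlation estimated for each list and with fry. Called members were counted with p-values adjusted over all genes and adjusted over the list alone. Annotation terms of 10 to 300 tested genes, taken from the deposited table, were tested with Fisher's exact test.

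Genes were named by a rule set beforehand. It took the 12 called genes with the largest rise and the 12 with the largest fall that had a mean of at least 5 FPKM in the higher group, groups that did not overlap and a symbol that is not a provisional identifier. It added up to 4 called members per list with the largest change, and 13 reference genes irrespective of result. Genes outside the rule are said in the text to have been chosen after their values were seen. Fold changes against a group at 0 in every library were computed against a floor of 3 counts over the pooled group. Where the span of a gene overlaps that of another expressed gene, reads could not be assigned by strand here. For genes named by the rule, an overlap is given beside the gene if the other gene had at least 10% of its mean count. Genes outside the rule were not checked for overlaps.

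Alternatives set beforehand were the FPKM pseudocount, filters on low values, TPM, median-of-ratios, upper-quartile and quantile scaling, variance models of limma, DESeq2 1.42.0, the replicate number as a block, leaving out each library, an estimated correlation, fry and annotation terms tested among all changed genes, without the 2-fold limit. Added as alternatives after seeing the data were limma on log2(FPKM + 1), library totals without a composition factor, libraries thinned to the smallest total, DESeq2 on all genes with a count, and a filter at 1 FPKM. The first of these, with a filter at 1 FPKM, had been planned as the main test for a table without counts. Figures were drawn with matplotlib 3.10.9. Raw reads were not analysed here. The results of 2 reference genes and of 1 list are not reported here.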

Results

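RNA was profiled in PANC-1 cells, an established human pancreatic ductal carcinoma line, after 48 h with 8 µM of a compound labelled CMR and in control cells. Each group held 3 libraries of poly(A)-selected RNA. The labels do not say what the control cells received, nor whether the libraries of a group came from separate cultures. The edgeR p-values therefore measure only the spread between these libraries, which may be technical. The camera p-values compare the genes of a list with the other genes, under a low preset correlation between genes. Fisher's exact test of annotation terms takes genes as its units. Very small p-values from camera or Fisher's test are therefore not evidence of that strength across 3 libraries per group. Library totals were 66460535, 70129221 and 68338576 counts for CMR and 51147268, 51715411 and 63811430 for control. Log expression correlated between libraries of a group with r from 0.966 to 0.971 and between groups with r from 0.914 to 0.939, across genes, which are not independent replicates.

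The comparison addressed which genes differed between PANC-1 cells with and without CMR. CMR-treated cells held more mRNA for endoplasmic reticulum (ER) chaperones, for the ATF4 branch of the stress response, for amino acid synthesis and transport and for antioxidant enzymes. They held less mRNA for DNA replication, mitosis, homologous recombination and the actin cytoskeleton. The replication list kept its call (adjusted p = 0.0463 with an estimated correlation), while the mitosis, recombination and actin lists lost theirs (adjusted p = 0.188, 0.172 and 0.213 with an estimated correlation). The ER chaperone gene HSPA5 was 11.5-fold higher, the stress transcription factor gene ATF3 22.5-fold higher, the heme oxygenase gene HMOX1 13.2-fold higher, the replication gene UHRF1 8.06-fold lower and the mitotic kinase gene CDK1 3.82-fold lower. Of 19200 genes tested, 7404 (38.6%) changed, 3928 higher and 3476 lower with CMR, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. A change of at least 2-fold was called in 3537 genes, 1895 higher and 1642 lower. With upper-quartile scaling, which moved the median log2 fold change of all tested genes by -0.13, the split was 3250 higher and 4324 lower. More genes were lower than higher also without a composition factor (3551 higher, 3903 lower). The same held with limma on FPKM values, as with quantile normalization (3131 and 3339). TPM (3451 and 2877), DESeq2 (4346 and 3956) and the other alternatives kept more genes higher. The balance therefore depends on the processing. The ranges of both groups did not overlap in 10345 genes (53.9%), where chance gives 10%. Among the 6480 genes with a mean of at least 5 FPKM (fragments scaled to gene length and library size), 3941 changed, 1234 of them at least 2-fold.

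ER chaperones and components of ER-associated degradation moved as a group. All 21 tested members rose, also when adjusted over the list alone, with a median log2 fold change of 1.83 (camera adjusted p = 1.8e-45; adjusted p = 0.0330 with an estimated correlation). HSPA5, the main Hsp70 chaperone of the ER lumen, averaged 8586 ± 339 normalised CPM (SD, n = 3) with CMR and 746 ± 42.5 in control (log2 fold change 3.52 ± 0.07 SE, edgeR adjusted p = 5.7e-06). HERPUD1, a membrane protein of ER-associated degradation, rose from 18.8 ± 2.48 to 259 ± 32.2 (log2 fold change 3.79 ± 0.15, edgeR adjusted p = 2.7e-05). DNAJB9, a co-chaperone of HSPA5, rose 14.3-fold and HYOU1, an ER chaperone, 8.61-fold. HSPA5 (ENSG00000044574) lies on the minus strand of chromosome 9 from 125234853 to 125241343, in the coordinates of the deposited table.

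The list of PERK-ATF4 stress response genes rose in 15 of 17 members, with 1 lower and 1 not called, the same counts as when adjusted over the list alone. Its median log2 fold change was 2.44 (camera adjusted p = 5.0e-40; adjusted p = 0.0308 with an estimated correlation). ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620772, plus strand) averaged 113 ± 16.3 with CMR and 5.02 ± 0.646 in control (SD, n = 3; log2 fold change 4.49 ± 0.16, edgeR adjusted p = 2.7e-05). CHAC1, which degrades glutathione, rose 13.4-fold, the lipoprotein receptor gene VLDLR 14.1-fold and the stress-induced regulator NUPR1 10.6-fold. DDIT3, the transcription factor CHOP, rose from 29.3 ± 1.57 to 172 ± 7.54 (log2 fold change 2.55 ± 0.09, edgeR adjusted p = 2.7e-05); its span overlaps those of MARS and MBD6. The member that fell, chosen after its values were seen, was the transcription factor gene ATF5 (log2 fold change -0.93, edgeR adjusted p = 0.0157). CDKN1A, the cyclin-dependent kinase inhibitor p21 and a member of this list, was not called (log2 fold change 0.57 ± 0.47, edgeR adjusted p = 0.377).

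Genes of amino acid synthesis and transport rose in 19 of 20 members, and in 20 of 20 when adjusted over the list alone. The median log2 fold change was 1.79 (camera adjusted p = 1.8e-32; adjusted p = 0.00816 with an estimated correlation). ALDH1L2, a mitochondrial folate enzyme whose span overlaps that of C12orf45, rose 36.1-fold (log2 fold change 5.17 ± 0.25). CTH, the cystathionine-cleaving enzyme that makes cysteine, rose from 1.69 ± 0.119 to 32.1 ± 4.08 (log2 fold change 4.25 ± 0.16, edgeR adjusted p = 2.7e-05). SLC7A11, the cystine-glutamate antiporter, rose from 58.6 ± 16.9 to 681 ± 123 (log2 fold change 3.54 ± 0.24, edgeR adjusted p = 0.000117), and the neutral amino acid transporter gene SLC1A4 rose 11.2-fold.

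Antioxidant genes regulated by NRF2 rose in 16 of 20 tested members and in 19 when adjusted over the list alone, with none lower. Their median log2 fold change was 1.62 (camera adjusted p = 1.0e-24; adjusted p = 0.0463 with an estimated correlation). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35390293, plus strand) averaged 513 ± 88.8 with CMR and 38.7 ± 6.58 in control (SD, n = 3; log2 fold change 3.73 ± 0.18, edgeR adjusted p = 4.9e-05). OSGIN1, an oxidative stress response gene, rose 11.4-fold, and GCLC, the catalytic subunit of the enzyme that limits glutathione synthesis, 6.04-fold.

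Autophagy and lysosome genes rose in 22 of 32 members and fell in 3, with 4 lower when adjusted over the list alone. The median log2 fold change was 0.64 (camera adjusted p = 7.8e-06; adjusted p = 0.0463 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose from 680 ± 36.2 to 2987 ± 210 (log2 fold change 2.13 ± 0.08, edgeR adjusted p = 2.7e-05). WIPI1, which acts at the forming autophagosome, rose 6.78-fold, MAP1LC3B, an autophagosome membrane protein gene whose span overlaps that of FBXO31, 4.16-fold and the initiating kinase gene ULK1 2.95-fold. Of the 3 that fell, the one with the largest fold, chosen after its values were seen, was TFEB, a transcription factor of lysosomal genes (log2 fold change -1.55, edgeR adjusted p = 0.0305).

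**Figure D1:**
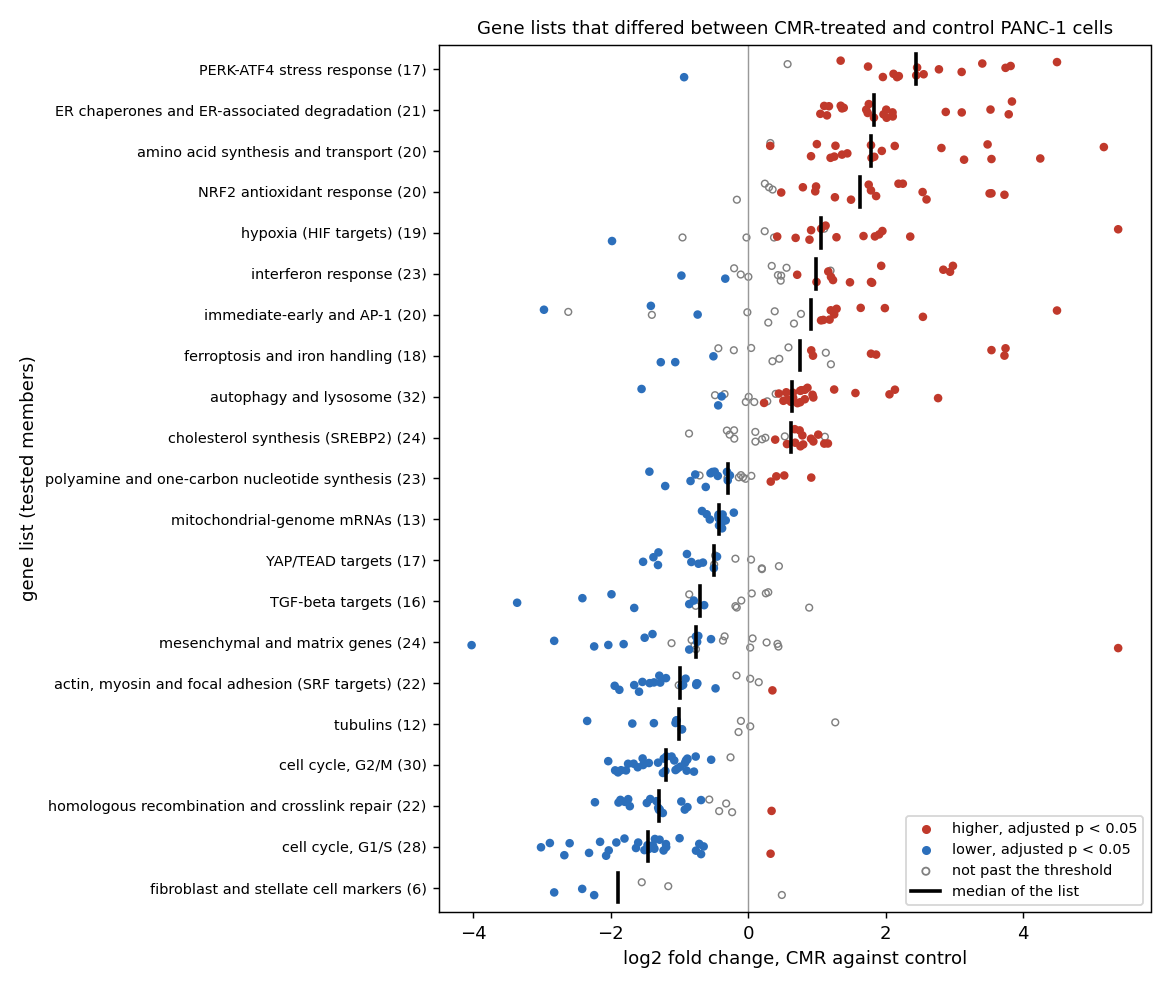
Log2 fold change of each tested member (points) of 21 of the 22 gene lists that camera called, CMR against control, 3 libraries per group; filled points passed an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), open points did not, and black bars are list medians. The PERK-ATF4 list had a median of 2.44 and the G1/S list of -1.45.

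Cell cycle genes fell with CMR. Of the 28 genes of the G1/S list, which encode replication and S-phase entry factors, 27 fell and 1 rose, also when adjusted over the list alone. Their median log2 fold change was -1.45 (camera adjusted p = 3.8e-25; adjusted p = 0.0463 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell from 82.1 ± 19.0 to 10.2 ± 1.06 normalised CPM (SD, n = 3; log2 fold change -3.01 ± 0.19, edgeR adjusted p = 9.0e-05). The transcription factor gene E2F8 was 7.38-fold lower, E2F2 6.37-fold lower and the replication initiation gene MCM10 6.04-fold lower. The member that rose, chosen after its values were seen, was CDC6, a replication licensing factor (log2 fold change 0.33, edgeR adjusted p = 0.0468).

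In the G2/M list 29 of 30 members fell, also when adjusted over the list alone, with a median log2 fold change of -1.20 (camera adjusted p = 7.4e-19; adjusted p = 0.188 with an estimated correlation). CDK1 (ENSG00000170312, chromosome 10, 60778331 to 60794852, plus strand) averaged 38.1 ± 11.8 with CMR and 146 ± 3.23 in control (SD, n = 3; log2 fold change -1.93 ± 0.23, edgeR adjusted p = 0.000807). TOP2A, a DNA topoisomerase of dividing cells, was 3.71-fold lower, the cytokinesis gene ANLN 4.10-fold lower, the kinase gene AURKB 3.60-fold lower and the proliferation marker MKI67 3.42-fold lower. Homologous recombination and crosslink repair genes fell in 17 of 22 members, and in 19 when adjusted over the list alone, with 1 higher. The median of that list was -1.29 (camera adjusted p = 9.0e-11; adjusted p = 0.172 with an estimated correlation). The helicase gene BRIP1 was 4.68-fold lower, the exonuclease gene EXO1 3.69-fold lower and the BRCA1 partner gene BARD1 3.62-fold lower. Polyamine and one-carbon nucleotide synthesis genes fell in 12 of 23 members and rose in 4, also when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.0384; adjusted p = 0.395 with an estimated correlation). That call was lost without control replicate 2 (camera adjusted p = 0.0605). In this list CTPS1, which makes CTP, was 1.79-fold lower and SAT1, a polyamine-acetylating enzyme, 1.89-fold higher.

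Cytoskeletal genes fell as well. The list of actin, myosin and focal adhesion genes had 17 of 22 members lower and 1 higher, with 18 lower when adjusted over the list alone. Its median log2 fold change was -0.99 (camera adjusted p = 1.3e-10; adjusted p = 0.213 with an estimated correlation). ACTG1, cytoplasmic gamma-actin, fell from 1862 ± 178 to 509 ± 97.1 (SD, n = 3; log2 fold change -1.87 ± 0.15, edgeR adjusted p = 0.000199). ACTB, beta-actin, was 2.70-fold lower, TAGLN2, an actin-binding protein gene, 3.15-fold lower, and the tropomyosin gene TPM1 lower by a log2 fold change of -1.59. The member that rose, chosen after its values were seen, was TLN1, which links integrins to actin (log2 fold change 0.35, edgeR adjusted p = 0.00529). Among tubulins, 7 of 12 fell, also when adjusted over the list alone, with a negative median (camera adjusted p = 5.4e-05; adjusted p = 0.220 with an estimated correlation). TUBB3 was 5.06-fold and TUBB4B 3.21-fold lower.

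TGF-beta target genes fell in 7 of 16 members and rose in none, also when adjusted over the list alone, with a median of -0.70 (camera adjusted p = 2.5e-05; adjusted p = 0.172 with an estimated correlation). The members with the largest falls were ID1 (10.3-fold lower), ID2 (5.31-fold) and ID3 (3.96-fold), inhibitors of basic helix-loop-helix factors that are also known targets of bone morphogenetic proteins. ID1 averaged 20.2 ± 4.43 with CMR and 207 ± 15.5 in control (SD, n = 3; log2 fold change -3.36 ± 0.18, edgeR adjusted p = 5.6e-05). YAP/TEAD target genes fell in 10 of 17 members, and in 11 when adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.000774; adjusted p = 0.344 with an estimated correlation). AXL, a receptor tyrosine kinase gene, was 2.88-fold lower and NT5E, a surface nucleotidase gene, 2.60-fold lower. Mesenchymal and matrix genes fell in 12 of 24 members and rose in 1, also when adjusted over the list alone, with a median of -0.76 (camera adjusted p = 0.00353; adjusted p = 0.296 with an estimated correlation). VIM, vimentin, fell from 3754 ± 37.3 to 1432 ± 211 (SD, n = 3; log2 fold change -1.39 ± 0.11, edgeR adjusted p = 0.000183) and COL1A1, a collagen chain gene, was 4.72-fold lower. The member that rose was LOX, a collagen-crosslinking enzyme gene whose span overlaps that of SRFBP1 on the other strand (41.6-fold higher).

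Epithelial genes went both ways, 10 of 24 lower and 4 higher, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.250). KRT19, a keratin of ductal epithelium, fell from 710 ± 7.78 to 141 ± 35.0 (SD, n = 3; log2 fold change -2.33 ± 0.17, edgeR adjusted p = 0.000152). KRT8 was 3.60-fold lower, MUC1 2.85-fold lower and the tight junction gene CLDN3 16.7-fold higher. KRT18, whose span overlaps that of KRT8, had a log2 fold change of -0.93 ± 0.24 (edgeR adjusted p = 0.0194), a call lost without CMR replicate 2 (0.0698), CMR replicate 3 (0.0576), control replicate 1 (0.0571) or control replicate 2 (0.0660).

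Hypoxia-inducible genes rose in 13 of 19 members and fell in 1, or 14 and 2 when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 2.7e-07; adjusted p = 0.177 with an estimated correlation). LOX was among them, and SLC2A1, the glucose transporter GLUT1, rose from 33.8 ± 2.33 to 173 ± 6.16 (SD, n = 3; log2 fold change 2.36 ± 0.09, edgeR adjusted p = 2.7e-05). EGLN3, an oxygen-sensing prolyl hydroxylase gene, was 3.94-fold lower. Glycolysis genes went both ways, 4 of 22 higher and 10 lower, or 4 and 11 when adjusted over the list alone, and were not called as a list (camera adjusted p = 0.341). Of these, the hexokinase gene HK2 was 10.6-fold higher, PDK1, which restrains pyruvate oxidation, 3.20-fold higher, and the lactate transporter gene SLC16A3, which overlaps CSNK1D, 3.19-fold lower. GAPDH had a log2 fold change of -0.50 ± 0.12 (edgeR adjusted p = 0.0141), a call lost without CMR replicate 2 (0.0520) or control replicate 1 (0.0538).

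The ferroptosis and iron list had 7 of 18 members higher and 3 lower, or 10 and 3 when adjusted over the list alone, with a median of 0.75 (camera adjusted p = 1.0e-05; adjusted p = 0.177 with an estimated correlation). Its risen members included SLC7A11, HMOX1 and CHAC1, given above, and the iron-storing ferritin light chain gene FTL (3.63-fold higher). GPX4, which reduces lipid peroxides and was chosen after its values were seen, fell (log2 fold change -0.50, edgeR adjusted p = 0.00932). Cholesterol synthesis genes rose in 13 of 24 members, and in 14 when adjusted over the list alone, with none lower and a median of 0.62 (camera adjusted p = 0.00444; adjusted p = 0.522 with an estimated correlation). SQLE, an early oxygen-requiring enzyme of the pathway, rose 2.15-fold and CYP51A1 2.03-fold. That list was not called among genes with a mean of at least 5 FPKM (camera adjusted p = 0.117). Fatty acid synthesis genes were 4 higher and 5 lower of 15, or 6 and 5 when adjusted over the list alone, without a call (camera adjusted p = 0.305); the list's median was -0.21, its mean 0.12 and its test direction upward. ME1, a source of NADPH, rose 4.55-fold.

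Interferon response genes rose in 12 of 23 members and fell in 2, or 15 and 2 when adjusted over the list alone, with a median of 0.99 (camera adjusted p = 0.000188; adjusted p = 0.188 with an estimated correlation). ISG20 was 7.88-fold higher, OASL 7.65-fold and IFI44 7.15-fold, while OAS3, chosen after its values were seen, was lower (log2 fold change -0.97, edgeR adjusted p = 0.000772). Immediate-early and AP-1 genes rose in 10 of 20 members and fell in 3, also when adjusted over the list alone, with a median of 0.91 (camera adjusted p = 0.00758; adjusted p = 0.188 with an estimated correlation). EGR1 was 3.97-fold higher and IER2 7.83-fold lower. Neither list was called among genes with a mean of at least 5 FPKM (camera adjusted p = 0.198 and 0.353). MYC, a growth-promoting transcription factor gene of the immediate-early list, was not called (log2 fold change 0.77 ± 0.35, edgeR adjusted p = 0.122), but passed with DESeq2 (adjusted p = 0.0443, or 0.0274 on every gene with a count).

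All 13 mRNAs encoded by the mitochondrial genome fell, also when adjusted over the list alone, with a median log2 fold change of -0.42 (camera adjusted p = 0.000417; adjusted p = 0.334 with an estimated correlation). They made up 3.75, 3.63 and 3.35% of counts in the CMR libraries and 5.22, 5.09 and 5.06% in the control libraries. MT-CO2, a subunit of cytochrome c oxidase, was 1.59-fold lower (log2 fold change -0.67 ± 0.07, edgeR adjusted p = 0.000424). The 2 mitochondrial ribosomal RNA genes, chosen after their values were seen, were higher instead, MT-RNR1 by 0.82 ± 0.15 (edgeR adjusted p = 0.00474) and MT-RNR2 by 0.71 ± 0.07 (edgeR adjusted p = 0.000408) on the log2 scale. Nuclear genes of oxidative phosphorylation were not called as a list (camera adjusted p = 0.238), with 10 of 28 lower and 1 higher, also when adjusted over the list alone.

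Several lists did not pass the list test. Metallothioneins and zinc response genes fell in 3 of 7 (camera adjusted p = 0.0531), with MT2A 2.65-fold and MT1E 3.01-fold lower. WNT targets fell in 3 of 10 (0.0626), among them DKK1, a secreted WNT inhibitor gene (3.73-fold lower). Cytosolic heat shock genes fell in 9 and rose in 3 of 17 (0.232). HSP90AA1 was 1.80-fold lower and the small heat shock gene HSPB8 3.71-fold higher. Proteasome genes rose in 9 of 24, or 12 when adjusted over the list alone, and fell in 1 (0.12), with PSMC4 2.18-fold higher. Apoptosis regulators rose in 9 of 27, or 10 when adjusted over the list alone, and fell in 4 (0.250). Xenobiotic response genes rose in 4 and fell in 2 of 8 (0.201). CYP1A1, a target of the aryl hydrocarbon receptor, averaged 6.83 ± 0.558 with CMR and 0.575 ± 0.333 in control (SD, n = 3; edgeR adjusted p = 0.000747). ERK output genes rose in 4 and fell in 7 of 16 (0.250). CCND1, cyclin D1, was 3.61-fold lower. NF-kB and inflammatory genes rose in 8 and fell in 5 of 18 (0.446). CCL2 was 3.01-fold lower and CXCL2 6.31-fold higher, while CCL20 and IL6, whose span overlaps that of AC073072, had no count in any control library and were at least 29.1-fold and at least 19.1-fold higher against a floor of 3 counts over the pooled controls. Those genes stayed scarce with CMR, at 0.508 ± 0.183 and 0.336 ± 0.0634 normalised CPM (SD, n = 3). The IL6 call was lost with the replicate number as a block (edgeR adjusted p = 0.0530).

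Further lists without a call were HLA class I antigen presentation (1 higher and 4 lower of 15, camera adjusted p = 0.460), fatty acid oxidation (3 higher and 4 lower of 15, 0.496), cholesterol efflux (2 higher and 2 lower of 10, 0.776), ribosome biogenesis and MYC targets (10 higher and 8 lower of 26, 0.511), cytosolic ribosomal proteins (1 higher and 2 lower of 32, 0.906) and senescence-associated secreted factors (5 higher and 4 lower of 13, 0.909). For the last 2 lists the median, mean and test also differed in sign. When adjusted over the list alone, fatty acid oxidation had 4 higher and ribosomal proteins none lower, with the other counts of these lists as given. RRP12, a ribosome biogenesis gene, was 5.16-fold higher and ANGPTL4, a secreted inhibitor of lipoprotein lipase, lower by a log2 fold change of -1.58.

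Of the tested markers of other cell types, 2 had a group mean above 5 FPKM. They were CD68, a lysosomal protein gene also expressed outside leukocytes (26.4 FPKM with CMR, 29.2 in control), and the fibroblast marker COL1A1 (6.50 FPKM in control, lower with CMR). Fibroblast and stellate cell markers fell in 3 of 6 tested, also when adjusted over the list alone (camera adjusted p = 0.0256; adjusted p = 0.188 with an estimated correlation). That call was lost without CMR replicate 1 (camera adjusted p = 0.0635), and its member COL1A1 is also in the mesenchymal list. THY1, a surface glycoprotein gene overlapping USP2-AS1, was 5.32-fold lower. Leukocyte markers (1 lower of 6, camera adjusted p = 0.248), islet and neuroendocrine markers (2 higher of 6, 0.511) and endothelial markers (1 higher of 6, 0.822) were not called. Acinar and erythroid markers had 2 tested genes each, too few for the list test, and both acinar genes rose. The trypsinogen genes PRSS2 and PRSS1, near-identical copies among which reads can be misassigned, had no control count and were at least 21.1-fold and at least 13.1-fold higher with CMR, with a mean of 0.232 FPKM for PRSS2 in the CMR libraries. The PRSS1 call was lost with the replicate number as a block (edgeR adjusted p = 0.0771). The erythroid genes HBA1 and HBA2 were not called (edgeR adjusted p = 0.546 and 0.478).

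**Figure D2:**
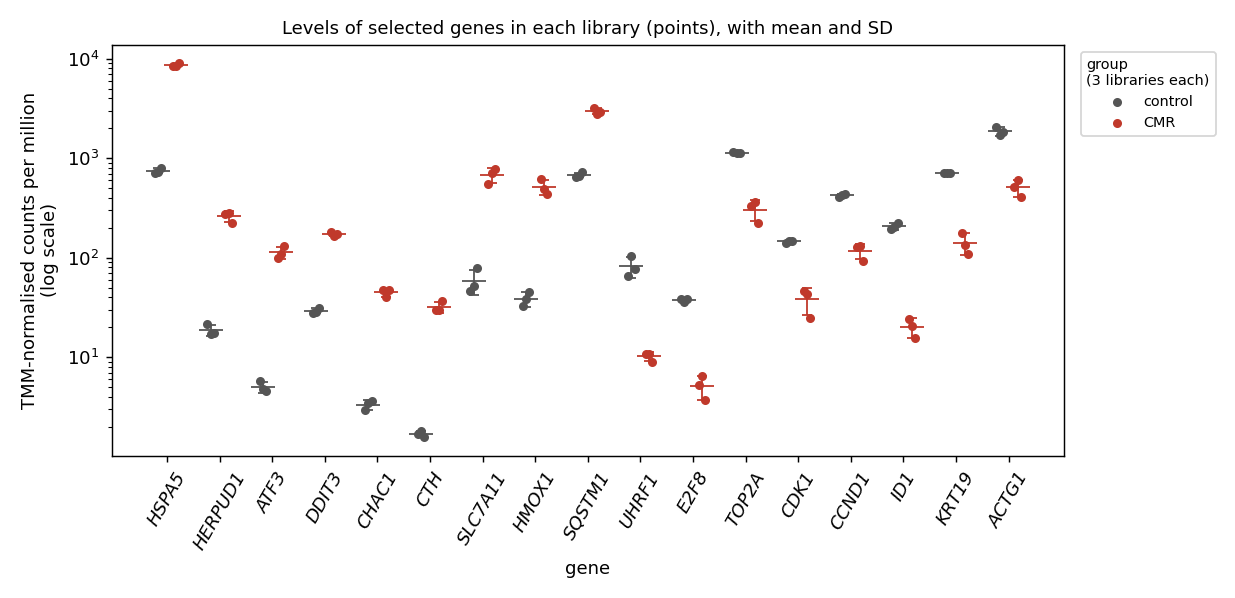
Normalised CPM (TMM scaling, log axis) of 17 genes in each of the 3 control and 3 CMR libraries (points), with mean (bar) and SD (whiskers). HSPA5 averaged 746 in control and 8586 with CMR, and the groups do not overlap for any gene shown.

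The 12 called genes with the largest rises among those with a mean of at least 5 FPKM in the higher group were led by BEX4 (70.5-fold), MFSD2A (65.6-fold), C17orf107 (57.5-fold) and FAM129A (44.5-fold). BEX4 (ENSG00000102409, chromosome X, 103215108 to 103217246, plus strand) averaged 23.1 ± 2.87 with CMR and 0.321 ± 0.168 in control (SD, n = 3; log2 fold change 6.14 ± 0.38, edgeR adjusted p = 8.3e-05). MFSD2A encodes a lysophospholipid transporter, and FAM129A a stress-induced protein. BEX2, another gene of the BEX family, rose 18.0-fold and JMY, an actin-nucleating factor gene, 17.9-fold. TMEM198, whose span overlaps that of CHPF, rose by a log2 fold change of 3.91, and RAB39B rose 40.2-fold (log2 fold change 5.33, or 6.20 without control replicate 3). The other genes of the 12 were LOX, ATF3, CTH and DNAJB9.

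Of the 12 genes with the largest falls by the same rule, 8 were small non-coding RNAs that carry no poly(A) tail. They were the RNA components of the ribonucleases MRP (RMRP) and P (RPPH1), the U1 and U2 spliceosomal RNA copies RNU1-2, RNU1-3, RNU1-4, RNU1-27P and RNU2-2P, and the 7SK RNA gene RN7SK. The remaining 4 were FAM111B, a replication-linked protease gene (12.2-fold lower), ID1, RASL11A (9.93-fold lower) and MIR1-1HG-AS1 (10.5-fold lower). RNU2-2P (chromosome 11, 62841619 to 62841809, within WDR74) averaged 0.0201 ± 0.00884 with CMR and 1.22 ± 0.519 in control (SD, n = 3; log2 fold change -5.79 ± 0.60, edgeR adjusted p = 0.000482). RPPH1 had a log2 fold change of -6.00 ± 0.77 (-6.93 without CMR replicate 2) and RNU1-4, within CROCC, of -5.18 ± 0.68. RMRP had a log2 fold change of -6.21, which was -4.68 without control replicate 1 and -7.52 without CMR replicate 2. The RN7SK call (log2 fold change -3.30 ± 1.02, edgeR adjusted p = 0.0385) was lost without CMR replicate 1 (0.102), CMR replicate 3 (0.113), control replicate 1 (0.0639) or control replicate 2 (0.126), and its log2 fold change was -4.80 without CMR replicate 2 and -2.18 without control replicate 2. The log2 fold change of RNU1-2, also within CROCC, was -5.37 (-7.20 without CMR replicate 2), of RNU1-3 -5.50 (-4.40 without control replicate 2) and of RNU1-27P -3.91 (-4.90 without CMR replicate 1). U1 copies are near-identical, so their separate counts are uncertain. In a wider set of 22 small RNA genes, put together after these values were seen, 15 were lower and 0 higher. The median log2 fold change of the 22 was -2.92, also with the gene at 0 in every CMR library set at its bound. U1 copies, and the copies RN7SL1, RN7SL2 and RN7SL3, count as separate genes here. The 15 and the median therefore do not rest on independent RNAs. The other 7 of the 22 were not called, with log2 fold changes from -1.92 (RNU1-28P) to 1.10 (RNU2-22P). Their mean control counts ran from only 4.67 to 16.3. A gene scarce in control can pass the low-count filter largely through its CMR counts, as RF00004 did. These 7 therefore give little on whether the fall was uniform.

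**Figure D3:**
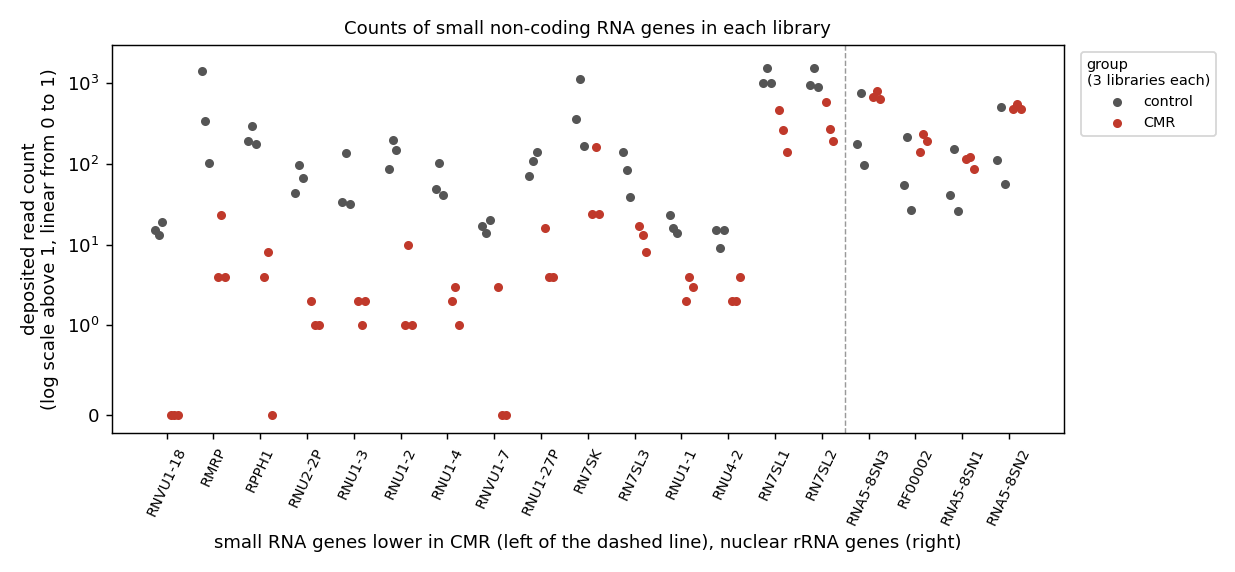
Deposited counts in each of the 3 control and 3 CMR libraries (points; log axis above 1, linear from 0 to 1) of the 15 small RNA genes that were lower with CMR and of 4 nuclear ribosomal RNA genes. The small RNA counts are higher in every control library than in every CMR library, and the ribosomal RNA counts overlap between groups.

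Gene Ontology terms given in the table were tested among genes changed at least 2-fold, against the 13759 tested genes that carry a term (one-sided Fisher's exact test, 3386 terms, Benjamini-Hochberg). Of these, 37 terms were enriched among higher genes and 133 among lower genes. Response to ER stress had 33 of 75 genes at least 2-fold higher, 3.99 times the expected number. PERK-mediated unfolded protein response had 9 of 12 and protein folding in the ER 10 of 16. Among lower genes, collagen-containing extracellular matrix had 60 of 223 genes (2.94 times the expected number), mitotic cell cycle 43 of 164, DNA replication 40 of 159 and intermediate filament 20 of 57. Without the 2-fold limit, 61 and 241 terms were enriched.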

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

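Across the alternatives, no gene called with all libraries and counts changed sign in the call. The count of changed genes (7404) lay between 5660 (without control replicate 1) and 8302 (DESeq2), apart from 3941 (2013 higher, 1928 lower) among genes with a mean of at least 5 FPKM, where only 6480 genes were tested. DESeq2 called 7388 of the 7404.

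The count of genes changed at least 2-fold (3537) moved more: 2283 with limma and a pseudocount of 0.1 FPKM, 2136 with TPM, 1507 with quantile normalization, 1538 without trend, 1532 with a robust variance model and 1234 at 5 FPKM. Among alternatives added after seeing the data it was 1539 with limma on log2(FPKM + 1), the test planned for a table without counts, and 2342 at 1 FPKM. The filters test fewer genes, and a pseudocount of 1 shrinks fold changes of scarce genes by construction. With the same filter at 1 FPKM, edgeR gave 2342, and limma gave 2283 at a pseudocount of 0.1 FPKM and 2389 at 0.01. Limma at a pseudocount of 1 FPKM gave 1539. Part of the fall therefore goes with the filter and a further part with the pseudocount. The variance models changed that count little (1538 and 1532). Leaving out a library gave 2901 (without CMR replicate 3) to 3907 (without CMR replicate 1).

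Of the 22 called lists, 6 stayed with an estimated correlation; fry called 33, and leaving out a library gave 21 to 24. The 5 FPKM filter ended the calls of 3 lists and made cytosolic heat shock pass (camera adjusted p = 0.0455; up to 0.522 over its alternatives). Metallothioneins (0.0531) passed without CMR replicate 3 (camera adjusted p = 0.0272), control replicate 1 (0.0446) or control replicate 3 (0.0313), with camera adjusted p from 0.0250 to 0.223 over the alternatives. WNT targets passed without control replicate 3 (camera adjusted p = 0.0408; 0.0200 to 0.221), and oxidative phosphorylation with limma and a pseudocount of 0.1 FPKM (camera adjusted p = 0.0422; up to 0.702). The cause was not tested. Fry, which tests against no change, passed 11 lists that camera had not called. It gave adjusted p = 0.0165 for heat shock, 0.00306 for metallothioneins and 0.00214 for WNT targets. The others were apoptosis regulators (fry adjusted p = 0.00197), proteasome (0.00221), leukocyte markers (0.00280) and islet markers (0.00426). Fry also passed glycolysis (adjusted p = 0.0145), fatty acid oxidation (0.0148), xenobiotic response (0.0233) and NF-kB genes (0.0449). With all changed genes in place of those changed at least 2-fold, 302 annotation terms were enriched instead of 170, of the same 3386 terms.

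With the replicate number as a replicate block, 6737 genes were called (3582 higher, 3155 lower) and 24 lists, the additions being metallothioneins (camera adjusted p = 0.0250) and WNT targets (0.0200); 6473 of the 7404 genes were kept. After each gene's group mean was subtracted, each CMR library correlated best with the control library of its own number (r = 0.0344, 0.0440 and 0.0520, against -0.0305 to -0.00989 for others). That is a weak hint from the data and not from the design. Subtracting the mean of 3 libraries forces high and low r values to balance, so some matching has to look best. Of 178 named genes, 154 had the same call under every alternative in which they were tested. The block ended 5 named calls, among them IL6 (edgeR adjusted p = 0.0530) and PRSS1 (0.0771).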

Other observations

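Genes of vesicle traffic between the ER and the Golgi were enriched among those at least 2-fold higher with CMR; the genes in this paragraph and the next were chosen after their values were seen. The ER-to-Golgi transport term had 50 of 172 genes at least 2-fold higher (2.64 times the expected number, Fisher adjusted p = 6.6e-08), and the COPII coat term 8 of 15. SEC24D, a cargo-binding subunit of that coat, averaged 26.1 ± 1.18 normalised CPM in control (SD, n = 3) and rose with CMR (log2 fold change 3.13 ± 0.12 SE, edgeR adjusted p = 2.7e-05). SEC24A had a log2 fold change of 2.51, and COPA, a subunit of the coat that returns vesicles to the ER, of 1.68. The ER stress sensor genes ERN1 (2.37), EIF2AK3 (3.04) and the transcription factor gene XBP1 (2.87) rose too.

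Genes of transmembrane receptor protein tyrosine kinase activity fell in 16 of 33 and rose in 3, with a median log2 fold change of -0.93. EPHA7, an ephrin receptor gene, fell from 21.5 ± 0.406 to 2.74 ± 0.953 (SD, n = 3; log2 fold change -2.97 ± 0.28, edgeR adjusted p = 0.000341). MET, the receptor of HGF, fell from 291 ± 5.20 to 157 ± 8.89, and its ligand gene HGF was 5.18-fold lower. INSR, the insulin receptor, rose (log2 fold change 1.58). Of 20 genes of the keratin filament term, 12 fell and 2 rose. KRT80 fell from 160 ± 8.60 to 33.7 ± 5.65.

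The explanations weighed next were written with their predictions before testing, except the tests of small RNAs against ribosomal RNA and against counting noise, which were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 7404 genes. The highest other split called 1 gene, and 10 splits are too few for a share under 0.05. Every other split mixes CMR and control libraries, so a group difference widens its spread and lowers its calls. The low counts of the other splits therefore add no support.

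The rise of the ER chaperone, ATF4, amino acid and NRF2 lists (77 genes, pooled median log2 fold change 1.83) stayed away from 0 after removing a trend on transcript length (1.79, SE 0.147), on GC content (1.84, SE 0.152) and with libraries thinned to equal totals without scaling (1.77, SE 0.147). The fall of the cell cycle lists (58 genes, -1.33) did so too: -1.40 (SE 0.10) for length, -1.41 (SE 0.0931) for GC content and -1.39 (SE 0.101) thinned. Of these lists, G1/S kept its call and G2/M lost it (camera adjusted p = 0.0463 and 0.188 with an estimated correlation). Across genes, log2 fold change had a Spearman rho of 0.0435 with length and -0.126 with GC content. With trends this weak and TMM factors from 0.960 to 1.03, these 3 technical sources had little room to move the medians, and both shifts stayed in place. The SEs treat the genes as independent. The estimated correlation within these lists ran from -0.0207 (amino acid list) to 0.517 (G2/M). Differences in culture or library preparation that follow the groups remain open.

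Small RNAs without a poly(A) tail (22 genes) had a median log2 fold change of -2.92. The set counts copies of the same RNA, such as those of U1, as separate genes, so its values are not independent. In 11 of the 15 lower genes the values did not rest on few control reads. Their mean control counts ran from 64 to 1184, over 3 times what the low-count filter asks. All 11 differed beyond counting noise (exact binomial test of pooled counts, largest Bonferroni p = 1.5e-46). That outcome was close to fixed, because edgeR had already called these genes against a wider spread. The pooled test therefore adds no support beyond the counts. For the other 4 lower genes, with mean control counts from 13 to 17.7, the same binomial test gave Bonferroni p from 3.0e-12 (RNVU1-18) to 0.0077 (RNU4-2). It has the same limit there, and those counts lie close to what the filter asks, so few reads stay open. Of the 22, 16 had a mean control count of at least 10 and groups that do not overlap, but the low-count filter asks for a mean of about 8.53 control counts of a gene under its limit in every CMR library (10 of the 22), and groups that do not overlap were part of the rule that brought the set up. Less carry-over of such RNA into the CMR libraries predicts that other classes fall too. The 3 tested snoRNA, scaRNA, Y and vault RNA genes outside other genes had a median of -1.56 (SE 0.992), which leaves that open. An equal loss of every RNA without a tail predicts the same fall of nuclear ribosomal RNA, but 4 ribosomal RNA genes had a median of 0.686 (SE 0.724), above the small RNAs. That median was 2.05 (SE 0.419) without control replicate 2 and 0.213 to 0.772 without another library, above the small RNAs by more than 3 SE each time. The genes behind it (RNA5-8SN1, RNA5-8SN2, RNA5-8SN3 and RF00002) are copies of the same short ribosomal RNA, and none was called. Their values are therefore not independent, and the comparison covers that RNA and not the larger ribosomal RNAs. For the 11 genes, a difference in the recovery of small RNA between the groups' preparations, or a biological fall of these transcripts may each account for the values, and these libraries do not separate them.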
